A study of Mus musculus with 2 samples.

How the data were processed

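The series holds single-cell RNA sequencing of NK cells sorted from bone marrow, spleen and MC38 tumours of mice. Per the labels, hashtagged cells of each condition were mixed and run on 1 lane of a 10X Genomics Chromium instrument, and the libraries were sequenced on a NovaSeq. The deposited matrix holds counts of UMIs per cell and gene, which were built with seqc per the labels' protocol, on mm10 per the submitters' processing notes. The authors also deposited a hashtag classification, a table that names the population of each hashtag, and cluster numbers for the cells. How the hashtags were classified and the cells were clustered is not given in the sources used here.

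The matrix had 13118 cells. Its 16800 gene columns carried 16789 symbols, and columns of the 11 repeated symbols were summed. Of the symbols, 16278 matched GENCODE M21, from which loci were taken. The deposited classification covered 13085 cells, and 33 cells had none. Cells called doublets were left out of every comparison, which left 7479 cells. Filters of at least 500 UMIs, at least 250 genes and at most 20% mitochondrial UMIs removed 0 of them.

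Cells were clustered to leave out other cell types. Counts were scaled to equal totals and log-transformed with scanpy 1.11.5, 2000 variable genes without mitochondrial and ribosomal protein genes gave 30 principal components, and 15 neighbours per cell were clustered with leidenalg 0.10.2 at resolution 0.8. Clusters named T cell-like, monocyte or macrophage-like, dendritic cell-like or neutrophil-like by their markers, 296 cells in all, were left out. The remaining 7183 cells were used. The name dendritic cell-like is uncertain, because the top genes of that cluster also held the macrophage genes Apoe, C1qa and C1qb. Its cells were left out under either name, dendritic cell-like or monocyte or macrophage-like. Other steps used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9. TMM factors came from edgeR 4.0.16.

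Because each population carried 1 hashtag, it was 1 sample. Counts were summed over its cells and scaled to CPM, and a difference was the log2 ratio of CPM + 5. The 95% interval of a gene comes from the binomial distribution of its counts given both totals, and that of a list median from 1000 Poisson draws. Both cover counting error only, and not differences between mice. Fixed lists of genes were summarised by the median over members at 20 CPM or more in at least 1 population, and placed among 10000 random lists matched for size and expression. Fasted, refed and ad libitum populations were compared within each tissue, tissues within ad libitum and fasted feeding, and the ad libitum with the naive spleen population. Shares of cells were counted after each cell was thinned to 1500 UMIs, with exact binomial intervals. On simulated Poisson counts with the totals of these populations, the gene intervals held the true ratio in 95.2% of genes in spleen, 95.7% in bone marrow and 95.4% in tumour. The simulation drew the counting error that the intervals assume and held no spread between cells. It therefore checks the computation and not whether the intervals are wide enough for these cells.

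The lists, comparisons, filters and the rule for named genes were fixed before the data were examined. In each diet comparison the rule took the 12 highest and 12 lowest log2 ratios among genes at 50 CPM or more in at least 1 population whose interval left out a ratio of 1. Unnamed gene models and mitochondrial, ribosomal protein, haemoglobin, immunoglobulin and T cell receptor genes were left out. For the tissues it took the 8 genes highest in each against the higher of the other 2. Up to 4 members per list and 18 genes of NK function were chosen to be named besides, of which 1 is not reported here. Alternatives chosen beforehand were TMM factors, totals without ribosomal protein and mitochondrial genes, a minimum of 1000 UMIs, every cell classified to 1 population, cells of other types kept, the mean over cells, thinned cells, equal cluster weights, other pseudocounts and minimum levels, other cluster resolutions, and cells that Scrublet predicts as doublets left out. After the data were seen, 3 more were added: low-RNA clusters left out, cells of highest Scrublet score left out, and each gene's highest cell left out.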

Results

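Natural killer (NK) cells, innate lymphocytes that kill stressed and transformed cells, were profiled by droplet-based single-cell RNA sequencing with unique molecular identifiers (UMIs). They came from bone marrow, spleen and subcutaneous MC38 tumours, a mouse colon carcinoma line. The C57BL/6 mice were 12 weeks old, and sorted cells lacked lineage markers and carried NK1.1 and CD49b. Cells of 10 populations were marked with hashtag antibodies, pooled, and run in 1 lane. Per the labels, mice were fed ad libitum or went through cycles of fasting, and the tag list of the deposit names an ad libitum, a fasted and a refed population for each of the 3 tissues and a further naive spleen population. What naive stands for and how many mice fed each population are not given in the sources used here. Each population was therefore 1 sample. No difference below has a replicate check, and no p-value was computed.

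The count matrix held 13118 cells and 16800 gene columns. The authors' hashtag classification gave 7479 cells to a single population and called 5606 cells (42.8% of those classified) doublets. The populations were very unequal in size although the labels describe mixing at equal ratios. A cluster of 45 cells named like group 1 innate lymphoid cells (ILC1) was kept among the NK cells. After cells of other types were left out, the spleen gave 1772 ad libitum, 1362 fasted, 1453 refed and 799 naive cells. The bone marrow gave 497, 120 and 281 cells in the order ad libitum, fasted and refed. The tumour gave 43, 765 and 91. Summed UMIs ranged from 546428 in the tumour ad libitum cells to 8668093 in the spleen ad libitum cells. Between them lay 621263 in the fasted bone marrow, 1204024 in the refed tumour, 2581174 and 4469842 in the refed and ad libitum bone marrow, and 3788137, 5208237, 5724161 and 7212987 in the naive spleen, fasted spleen, fasted tumour and refed spleen. Median UMIs per cell were lower in the fasted than in the ad libitum population in spleen (3448.5 against 4197) and in bone marrow (4327.5 against 6846), and higher in tumour (5293 against 3863).

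Values are CPM, the UMIs of a gene summed over a population and scaled to the same total in each, and differences are log2 ratios of CPM + 5. A pair of numbers after a log2 ratio is its 95% interval, which covers counting error only. For a gene list, the median over its measured members is followed by such an interval and by its percentile among 10000 random lists of the same size and expression, given as a description of these populations. Where the cell with most UMIs of a gene changed a log2 ratio by a factor of more than 1.5 or turned it, the ratio without that cell in either population is given too, and likewise for the median of a list, a choice made after the data were seen. Where the interval left out 0, values that turned direction under the same weight per cell, thinned cells, equal cluster weights or kept cells of other types stand beside the ratio. Equal cluster weights mean that each cluster with at least 5 cells in both populations counted alike in them. Cells of all other clusters were left out, so such a value can rest on a part of each population.

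The first question was how NK cells of the 3 tissues differed under ad libitum feeding. Spleen cells stood out for genes of mature circulating NK cells, bone marrow cells for genes of dividing cells, and tumour cells for granzymes that resting NK cells hardly express. In spleen these included Cx3cr1, a chemokine receptor of mature NK cells (log2 ratio 2.68, 2.34 to 2.99 against the next highest tissue), and S1pr5, a sphingosine-1-phosphate receptor needed to leave bone marrow (log2 ratio 2.22, 1.99 to 2.46). The further spleen genes were Ly6c2 (2.70), Kcnj8 (2.60), Cma1 (2.09), Zeb2 (2.02), a transcription factor of terminal NK maturation, Ccl3 (1.90) and Itgam (1.79). In bone marrow they were the proliferation marker Mki67 (log2 ratio 1.85, 1.49 to 2.23, 2.90 without its highest cell), the mitotic genes Nusap1 (1.92, -1.20 with equal cluster weights) and Fbxo5 (1.90, -0.34 with equal cluster weights), and the replication-dependent histone genes Hist1h2ae (2.22, -0.03 with equal cluster weights), Hist1h1b (2.01, 3.89 without its highest cell), Hist1h2ab (2.00, -0.32 with equal cluster weights), Hist1h2ap (1.98, 3.13 without its highest cell) and Hist1h2bj (1.84, -0.04 with equal cluster weights). In tumour they were the granzyme genes Gzmd (log2 ratio 7.99, 7.78 to 8.20), Gzme (7.78, -0.58 with equal cluster weights), Gzmc (6.62), Gzmg (5.24, -0.32 with equal cluster weights) and Gzmf (4.65, 2.83 without its highest cell, -1.47 with equal cluster weights), the secreted phosphoprotein Spp1 (6.08), and the interferon-inducible genes Ifitm2 (5.71) and Ly6a (4.66). Gzmc reached 22479 CPM in tumour against 224 in spleen. Of the Gzmd UMIs of the tumour cells, 42.2% came from 1 cell, as did 73.5% of Gzmf, 69.4% of Gzmg and 44.9% of Spp1. Without each gene's highest cell the log2 ratios were 7.36 for Gzmd, 3.62 for Gzmg and 5.58 for Spp1. Between bone marrow and tumour, equal cluster weights rested on shared clusters with 7 and 5 bone marrow cells. Between tumour and spleen they left out the cluster led by granzyme genes (15 tumour and 4 spleen cells) and the largest spleen clusters (1138 and 347 cells). The turned values of these comparisons therefore do not speak for the whole populations.

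Fixed lists of genes for maturation, division and metabolism also differed between tissues. The mature NK genes were lower in bone marrow than in spleen (12 of 12 measured members lower, median -1.44, -1.52 to -1.34, percentile 0) and lower in tumour than in spleen (9 of 12 measured members lower, median -1.44, -2.03 to -1.02, percentile 0). Dividing genes were higher in bone marrow (11 of 11 measured members higher, median 2.11, 2.03 to 2.22, percentile 100.0). With equal cluster weights the bone marrow medians were -0.21 for the mature NK and -0.22 for the dividing genes. MYC and nucleolar growth genes were also higher in bone marrow (15 of 15 measured members higher, median 0.88, 0.80 to 0.95, percentile 100.0), and glucocorticoid targets were lower (7 of 9 measured members lower, median -1.001, -1.07 to -0.85, percentile 0, -0.16 with equal cluster weights). Against spleen, tumour cells had higher interferon-induced genes (14 of 14 measured members higher, median 1.63, 1.498 to 1.95, percentile 100.0), glycolysis genes (12 of 15 measured members higher, median 1.86, 1.63 to 1.98, percentile 100.0), sterol and fatty acid synthesis genes (11 of 12 measured members higher, median 1.36, 1.04 to 1.64, percentile 100.0), hypoxia genes (11 of 13 measured members higher, median 1.252, 0.94 to 1.57, percentile 100.0) and genes of the TGF-beta response and tissue residency (7 of 8 measured members higher, median 1.20, 1.01 to 1.39, percentile 100.0). With equal cluster weights the tumour medians were 1.08, 0.55, 0.22, 0.48 and 0.27 in that order. They rested on shared clusters with 19 and 7 tumour cells. The interferon-induced median was 2.82 with the same weight per cell. Scaling with TMM factors moved the median of all genes by 0.20 for tumour against spleen and by 0.18 for tumour against bone marrow. Leaving ribosomal protein and mitochondrial genes out of the totals moved it by 0.11 for tumour against spleen and 0.11 for bone marrow against spleen.

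The main question of the design was how NK cells of fasted and ad libitum mice differed in each tissue. In the fasted spleen population, genes induced by glucocorticoid hormone were higher than in the ad libitum population. Among genes at 50 CPM or more in either population, the highest ratio was that of Pik3ip1, an inhibitor of phosphoinositide 3-kinase (log2 ratio 1.90, 1.67 to 2.13, 79.1 against 17.5 CPM). It was followed by Tsc22d3, the glucocorticoid-induced leucine zipper (log2 ratio 1.31, 1.19 to 1.43, 257 against 100.4 CPM), Rab27a, a small GTPase of cytotoxic granule release (1.26, 1.05 to 1.47), Txnip, which restrains glucose uptake (log2 ratio 1.18, 1.10 to 1.26, 545 against 238 CPM), and Fkbp5, a co-chaperone of the glucocorticoid receptor (1.07, 0.86 to 1.27). Cpt1a, which brings long-chain fatty acids into mitochondria for oxidation, was higher too (log2 ratio 1.33, 1.07 to 1.59, 42.6 against 14.0 CPM). On the mouse assembly mm10 (GENCODE M21 gene models) Pik3ip1 lies on chromosome 11 from 3330401 to 3342971, Tsc22d3 on chromosome X from 140539528 to 140600659, and Cpt1a on chromosome 19 from 3322334 to 3385733. The glucocorticoid list was higher as a group (9 of 12 measured members higher, median 0.77, 0.66 to 0.92, percentile 100.0, 0.49 without a minimum level, 1.08 with thinned cells). Il7r, the interleukin 7 receptor gene (1.21), belongs to it and to the immature NK list, which was higher too (9 of 11 measured members higher, median 0.30, 0.20 to 0.41, percentile 100.0). The highest genes further held Klhl6 (0.97), Acp5 (0.89), Serinc3 (0.83), Cxcr4 (0.76), Arhgap26 (0.73), Zfp36l2 (0.73) and Qrfp (0.71).

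Lower in the fasted spleen were genes of cell division, of mature and effector NK cells and of oxidative phosphorylation. Dividing genes were lower as a group (10 of 10 measured members lower, median -0.79, -0.92 to -0.68, percentile 0), with Mki67 (-1.41, 0.11 with equal cluster weights), Top2a (-1.23) and Birc5 (-0.96, 0.17 with equal cluster weights) among the lowest of all genes. With equal cluster weights the dividing median was 0.09. The dividing-like cluster (36 ad libitum and 4 fasted cells) and a cluster led by replication genes (29 and 2) had fewer than 5 fasted cells. All values under equal cluster weights in this comparison therefore left them out, and do not show that the decrease vanished. Mature NK genes were lower (10 of 12 measured members lower, median -0.25, -0.30 to -0.20, percentile 0.0300), led by Cx3cr1 (-1.17, -1.41 to -0.94). Cytotoxic effectors were lower (11 of 12 measured members lower, median -0.20, -0.25 to -0.16, percentile 0.630), with the granzyme genes Gzmm (-0.73) and Gzmb (-0.43) and perforin, Prf1 (-0.26). Of the cytokines and chemokines (6 of 9 measured members lower, median -0.14, -0.34 to -0.01, percentile 5.26), Xcl1, which attracts cross-presenting dendritic cells, was -0.93, Ccl3 -0.72 and Ccl4 -0.66. Slightly lower were oxidative phosphorylation (28 of 29 measured members lower, median -0.22, -0.25 to -0.19, percentile 0), MYC and nucleolar growth genes (12 of 14 measured members lower, median -0.24, -0.31 to -0.15, percentile 0.0200) and interferon-induced genes (5 of 5 measured members lower, median -0.42, -0.52 to -0.28, percentile 0.0200). The fatty acid oxidation list as a whole lay at the centre of random lists (11 of 17 measured members higher, median 0.03, -0.03 to 0.14, percentile 56.9), with Slc25a20, the mitochondrial carnitine carrier (0.79), Acaa2 (0.54) and Hadh (0.41) beside Cpt1a. PPAR targets, which hold Cpt1a and Slc25a20 too, were higher (4 of 5 measured members higher, median 0.22, 0.14 to 0.31, percentile 98.1). The lowest genes further held Tuba1b (-0.99), Gzmc (-0.98, 0.05 with the same weight per cell, 0.17 with equal cluster weights), Ube2c (-0.88, 0.15 with equal cluster weights), Slamf7 (-0.88), Tnfrsf9 (-0.82), S100a4 (-0.78) and Stmn1 (-0.77, 0.05 with equal cluster weights). Among genes of NK identity and function chosen beforehand, Klf2 (0.06, -0.01 with the same weight per cell, -0.02 with thinned cells), Il12rb2 (0.02), Cd27 (0.35) and Ccl5 (0.23) were higher. Lower were S1pr5 (-0.16), Ifng (-0.31), Gzma (-0.15), Tbx21 (-0.11), Eomes (-0.03), Itgam (-0.04), Klrg1 (-0.44) and Cd69 (-0.14). The share of UMIs from Gm42418, AY036118 and Lars2, which carry or collect ribosomal RNA reads, was 2.62% in the fasted and 2.17% in the ad libitum spleen.

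Higher in the fasted than in the ad libitum bone marrow population were Il7r (log2 ratio 2.75, 2.23 to 3.23, 74.0 against 6.71 CPM), Pik3ip1 (2.24, 1.74 to 2.72), Tsc22d3 (log2 ratio 1.94, 1.62 to 2.25, 196 against 47.7 CPM), Txnip (1.58) and Cpt1a (log2 ratio 1.67, 1.05 to 2.26, 40.2 against 9.17 CPM). As a group the glucocorticoid targets were higher (9 of 10 measured members higher, median 1.18, 0.97 to 1.47, percentile 100.0), as were genes of FOXO and KLF2 quiescence (14 of 14 measured members higher, median 0.62, 0.39 to 0.72, percentile 100.0) and immature NK genes (10 of 11 measured members higher, median 0.65, 0.43 to 0.87, percentile 100.0). With equal cluster weights the medians of these 3 lists were 1.247, 0.22 and 0.27. Il7r, on chromosome 15 from 9505788 to 9530176, is a member of all 3 lists. The ratios of 9 further genes lay above it, all of them genes of neutrophil granules or inflammation: S100a9 (8.10, 0.44 without its highest cell), S100a8 (7.79, 0.34 without its highest cell), Camp (7.50, 0.45 without its highest cell), Ngp (6.90, -0.39 without its highest cell), Lcn2 (6.57, -0.18 without its highest cell), Chil3 (6.23, -0.24 without its highest cell), Ltf (5.11, 0 without its highest cell), Lyz2 (5.10, -0.51 without its highest cell, -0.54 with other cell types kept) and Wfdc21 (4.64, -0.18 without its highest cell). A single cell carried 99.6% of the S100a9 UMIs of the fasted population, and neutrophil markers summed to 11921 CPM against 55.9 CPM. Serpinb1a (2.40, 0.85 without its highest cell) completed the highest genes.

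In bone marrow the lowest genes included genes of DNA replication and of dividing cells. Lowest was Mcm5, a subunit of the replicative helicase (log2 ratio -2.14, -2.87 to -1.43, 17.7 against 95.1 CPM), followed by Hells (-1.91), the thymidine kinase gene Tk1 (-1.87) and the clamp loader gene Rfc4 (-1.83). The dividing genes were lower as a group (11 of 11 measured members lower, median -1.02, -1.16 to -0.93, percentile 0), with a median of 0.12 under equal cluster weights. That last value left out the cluster led by replication genes, with 63 ad libitum and 0 fasted cells. Growth and biosynthesis genes were lower too: MYC and nucleolar growth (14 of 15 measured members lower, median -0.77, -0.95 to -0.66, percentile 0), oxidative phosphorylation (28 of 29 measured members lower, median -0.47, -0.52 to -0.40, percentile 0.0200), glycolysis (11 of 13 measured members lower, median -0.50, -0.65 to -0.26, percentile 0.430) and the ATF4 amino acid response (7 of 9 measured members lower, median -0.67, -1.15 to -0.26, percentile 0.155), in which Mthfd2 was -1.83, Psat1 -1.38 and Phgdh -1.37. Mature NK genes were lower (8 of 11 measured members lower, median -0.32, -0.57 to -0.13, percentile 4.87, -0.48 without each gene's highest cell), with Klrg1, an inhibitory receptor of late NK cells (-1.505, -2.30 to -0.68), and Gzmb (-1.36, -1.61 to -1.11) at the bottom. The lowest genes further held Lyar (-1.73), Sdf2l1 (-1.71), Aurkb (-1.70), Ccnb1 (-1.68, -2.72 without its highest cell), Ppa1 (-1.66), Asf1b (-1.52), Dut (-1.52) and Hist1h2ae (-1.47). Among the NK genes chosen beforehand, Cxcr4 (1.07), Klf2 (0.06, 0.01 without its highest cell), Tbx21 (0.08, -0.01 without its highest cell), Eomes (0.16), Cd27 (0.80), Itgam (0.51), Ccl5 (0.63) and Cd69 (0.35) were higher. Lower were S1pr5 (-0.27, -0.51 without its highest cell), Ifng (-0.91), Il12rb2 (-0.60), Gzma (-0.47) and Prf1 (-0.39). The low-RNA cluster led by Gm42418 held 19.9% of the fasted and 3.48% of the ad libitum singlets, and Gm42418, AY036118 and Lars2 took 2.70% and 1.79% of UMIs.

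In tumour, the fasted population had higher Cxcr4, Tsc22d3, Klf2 and Ccl5 and lower Gzmd, Gzme, glycolysis and sterol synthesis genes than the ad libitum population. They included Cxcr4, a chemokine receptor that keeps NK cells in bone marrow (log2 ratio 2.30, 1.86 to 2.78, 345 against 65.9 CPM), and Tsc22d3 (log2 ratio 1.98, 1.56 to 2.43, 311 against 75.0 CPM). Klf2, a transcription factor of lymphocyte quiescence and recirculation (log2 ratio 1.78, 1.498 to 2.08, 622 against 178 CPM), and Ccl5, a chemokine for T cells (log2 ratio 1.48, 1.40 to 1.55, 7263 against 2608 CPM), were higher too. Cxcr4 lies on chromosome 1 from 128588199 to 128592293. Glucocorticoid targets were higher as a group (8 of 12 measured members higher, median 0.63, 0.32 to 0.84, percentile 100.0, 1.13 without each gene's highest cell), and 0.26 when every cell had the same weight. Genes of FOXO and KLF2 quiescence were higher (8 of 12 measured members higher, median 0.77, 0.49 to 1.01, percentile 100.0), but 0.12 with the same weight per cell. Immediate early and heat shock genes (14 of 18 measured members higher, median 0.54, 0.40 to 0.71, percentile 100.0, 0.96 without each gene's highest cell, 0.09 with the same weight per cell) and cytokines and chemokines (7 of 9 measured members higher, median 0.61, 0.43 to 0.92, percentile 100.0, 0.18 with the same weight per cell) were higher too. The TGF-beta and residency list (7 of 8 measured members higher, median 0.54, 0.39 to 0.68, percentile 99.9) and NF-kB targets (10 of 11 measured members higher, median 0.41, 0.25 to 0.71, percentile 99.8, 0.79 without each gene's highest cell, 0.22 with the same weight per cell) had higher medians. The chemokine genes Ccl4 (1.35) and Ccl3 (1.06, 1.6003 without its highest cell) were members of the cytokine and chemokine list. Cd69, a member of the TGF-beta and residency list, depended on the setting (0.84, 1.31 without its highest cell, -0.23 with thinned cells, -0.29 with equal cluster weights). The highest genes further held Ccl1 (3.36), Pdcd4 (1.72), Pim2 (1.63), Bcl2 (1.58), Klhl6 (1.56), Arhgap17 (1.502), Zfp36l2 (1.49) and Ly6c2 (1.43, 2.27 without its highest cell). Only 43 ad libitum cells stand behind these ratios. The cluster led by granzyme genes, with a median of 25808.5 UMIs per cell, held 32.6% of the ad libitum tumour singlets. It held 9.74% of the fasted and 35.8% of the refed ones. Summed counts weigh its cells by their UMIs, and whether the granzyme and Spp1 ratios reflect its share was not tested. The shares of this cluster are shares of singlets only. Among singlets of the authors' clusters 0, 8 and 11, 86.0, 84 and 95.5% were tumour cells. In these clusters 80.2, 59.0 and 62.4% of cells were called doublets, against 42.8% of all classified cells. How leaving them out changed the tumour populations was not tested.

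The lowest genes of the fasted tumour cells were Spp1 (log2 ratio -3.94, -4.08 to -3.80, 119 against 1901 CPM), Gzme (log2 ratio -3.09, -3.20 to -2.97, 229 against 1987 CPM) and Gzmd (log2 ratio -2.93, -3.01 to -2.86, 559 against 4301 CPM). A single ad libitum cell held 44.9% of the Spp1 UMIs, 51.1% of Gzme and 42.2% of Gzmd. Glycolysis genes were lower (12 of 14 measured members lower, median -0.98, -1.05 to -0.87, percentile 0, -0.41 with equal cluster weights), led by the lactate exporter gene Slc16a3 (-2.11) and by Pgam1 (-1.20), Pkm (-1.12) and Ldha (-1.08). Sterol and fatty acid synthesis genes were lower (11 of 11 measured members lower, median -0.98, -1.253 to -0.73, percentile 0, -0.59 with equal cluster weights), led by Scd2 (-1.80), Fdps (-1.46), Cyp51 (-1.45, -0.88 without its highest cell, 1.52 with thinned cells from 10 against 0 UMIs) and Hmgcs1 (-1.20, -0.71 without its highest cell, 1.52 with thinned cells from 10 against 0 UMIs). Hypoxia genes (11 of 13 measured members lower, median -0.54, -0.78 to -0.21, percentile 0, -0.15 without each gene's highest cell, -0.24), mature NK genes (5 of 7 measured members lower, median -0.46, -0.51 to -0.38, percentile 0.455, -0.22 without each gene's highest cell, 0.00397 without a minimum, -0.29) and dividing genes (11 of 11 measured members lower, median -1.14, -1.34 to -0.84, percentile 0, -0.59 without each gene's highest cell, 0.16) were lower as well. Each of these 3 has its median under equal cluster weights given last. Those medians left out the dividing-like cluster, with 1 ad libitum and 3 fasted cells. The lowest genes further held Fabp5 (-2.49, -0.06 without its highest cell), Cdca3 (-2.23), Ifitm2 (-2.22), Cenpf (-2.19, -0.66 without its highest cell), Myo10 (-2.18), Tmsb15a (-2.18, -1.33 without its highest cell), Basp1 (-2.09) and Adam8 (-1.92). Of the NK genes chosen beforehand, Ifng (0.61), Il12rb2 (0.35, 0.63 without its highest cell), Gzma (0.56, 0.89 without its highest cell), Tbx21 (0.17, 0.44 without its highest cell) and Cd27 (0.29, 0.66 without its highest cell) were higher. Lower were Gzmb (-0.46, -0.22 without its highest cell), Prf1 (-1.08), Eomes (-0.44, -0.28 without its highest cell, 0.16 with thinned cells) and Klrg1 (-1.05).

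**Figure D1:**
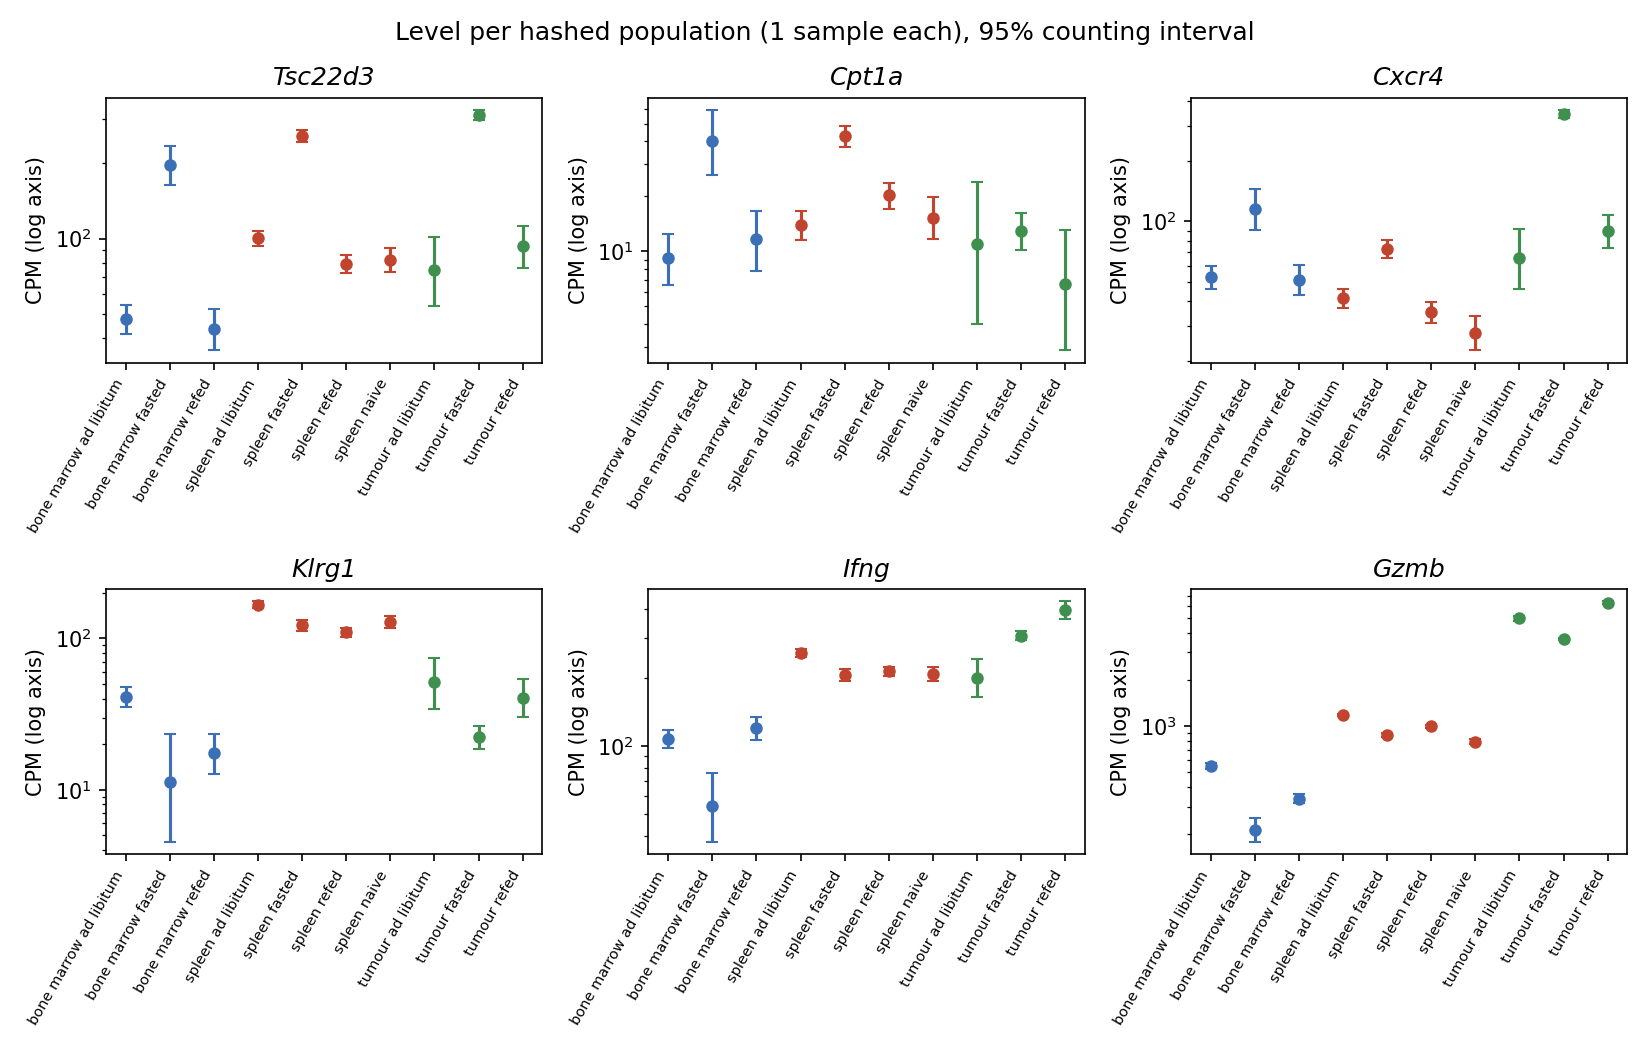
CPM on a log axis of 6 genes in the 10 hashed populations. Points are summed counts over 1 population each and bars are 95% counting intervals. Tsc22d3 was higher in the fasted than in the ad libitum population of bone marrow (196 against 47.7 CPM), spleen (257 against 100.4 CPM) and tumour (311 against 75.0 CPM).

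Across tissues the fasting ratios of single genes went together. Over 2393 genes, Spearman's correlation of the fasted against ad libitum ratios was 0.69 between bone marrow and spleen. It was 0.43 between tumour and spleen (2072 genes) and 0.49 between bone marrow and tumour (2157 genes). These correlations run across genes, which are not independent replicates. The glucocorticoid targets measured in both tissues differed by a median of 0.49 (0.31 to 0.63) between the bone marrow and the spleen ratio, and by 0.40 (0.05 to 0.81) between the tumour and the spleen ratio. The latter was -0.27 with the same weight per cell and -0.46 with equal cluster weights, but 0.94 without each gene's highest cell. The bone marrow difference was 0.04 with equal cluster weights and 0.14 both with the same weight per cell and with thinned cells. Ifng, which encodes interferon gamma, differed between tissues: its fasting ratio was -0.91, -1.41 to -0.45 in bone marrow, -0.31, -0.41 to -0.20 in spleen and 0.61, 0.33 to 0.89 in tumour. Gzma, the most abundant granzyme gene of spleen NK cells, was -0.47 in bone marrow, -0.15 in spleen and in tumour 0.56, 0.89 without its highest cell.

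**Figure D2:**
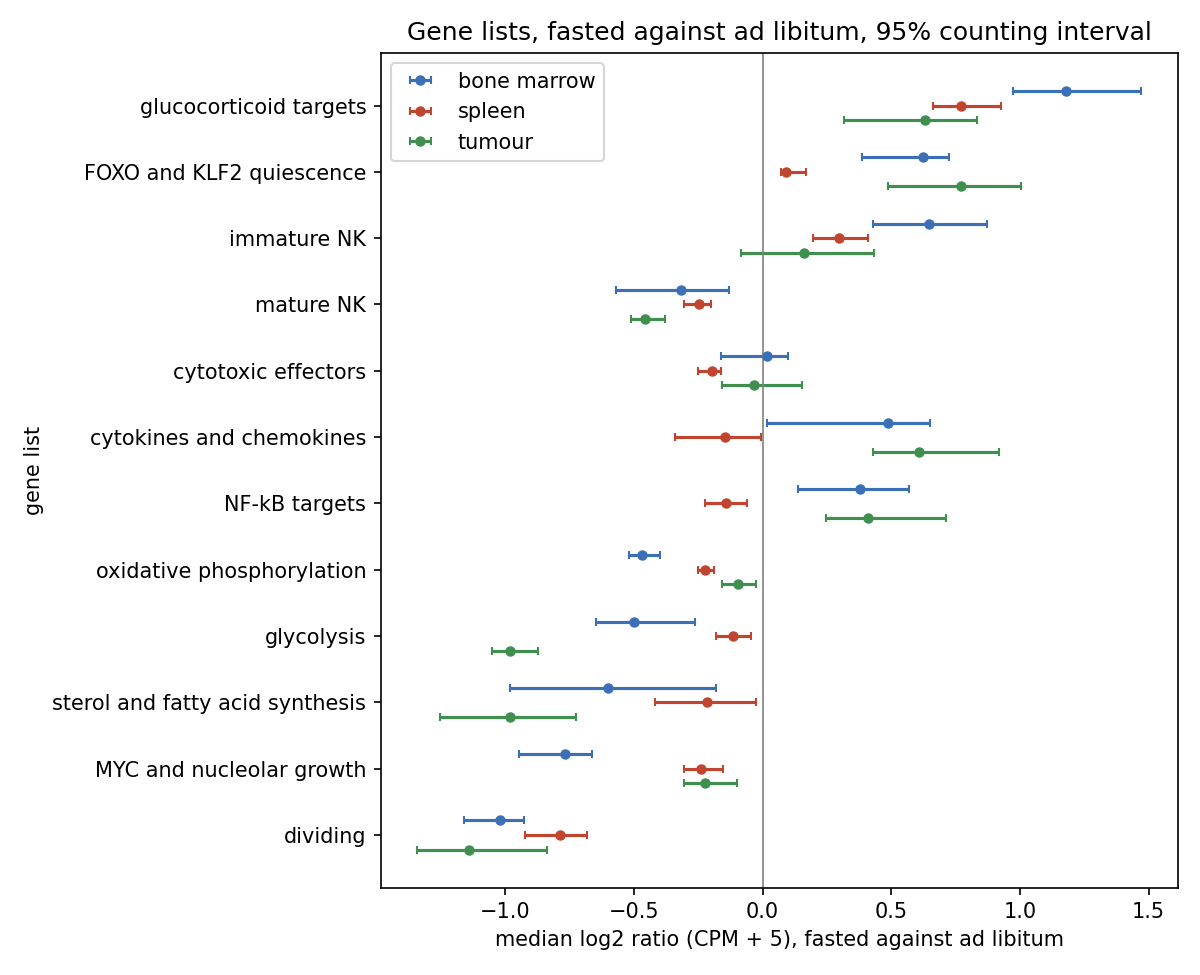
Median log2 ratio (CPM + 5) of the measured members of 12 gene lists, fasted against ad libitum, in bone marrow, spleen and tumour. Bars are 95% intervals for counting error and the vertical line marks a log2 ratio of 0. Glucocorticoid targets lay above 0 in all 3 tissues (1.18, 0.77 and 0.63), and dividing genes below it.

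**Figure D3:**
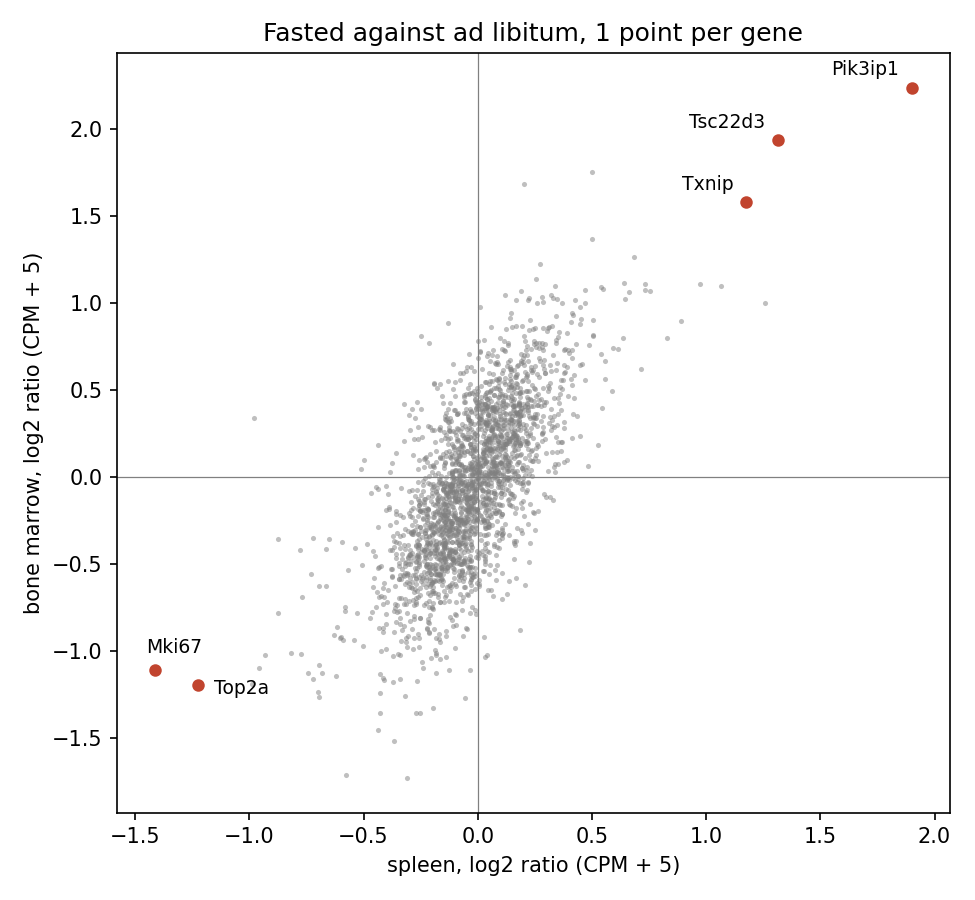
Fasted against ad libitum log2 ratio (CPM + 5) of single genes in spleen (x axis) and bone marrow (y axis), 1 point per gene at 50 CPM or more in both comparisons. Pik3ip1, Tsc22d3 and Txnip lay in the upper right and Mki67 and Top2a in the lower left.

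A comparison of the refed with the ad libitum populations asks what was left after feeding resumed. It shares each ad libitum sample with the fasted comparison, so a trait of that sample appears in both with the same sign. In spleen, Klrg1 was 167 CPM ad libitum, 122 fasted, 110 refed and 129 naive, and Prf1 377, 314, 319 and 310. Tsc22d3 differed from this, with 100.4, 257, 78.9 and 82.4 CPM. Lower ratios in both comparisons therefore do not alone show an effect that lasted after refeeding. In spleen, glucocorticoid targets were lower than in the ad libitum population. Among the chaperone and co-chaperone genes, higher ones were Hsph1 (0.79, 0.60 to 0.98), Dnaja1 (0.58), Stip1 (0.56), Hspa8 (0.52), Hsp90aa1 (0.51), Hsp90ab1 (0.45) and Dnajb1 (0.43). The immediate early and heat shock list was divided (10 of 18 measured members higher, median 0.27, 0.16 to 0.37, percentile 100.0, 0.15 with a minimum of 10 CPM), with Hspa1b (1.71) and Hspa1a (1.59) among the higher members. Glucocorticoid targets were lower (7 of 9 measured members lower, median -0.27, -0.31 to -0.20, percentile 0), with Sgk1 (-0.58), Ddit4 (-0.42) and Tsc22d3 (-0.33). Cx3cr1 (-1.08, -1.29 to -0.88) and Klrg1 (-0.58, -0.70 to -0.46) were lower, as were mature NK genes as a group (11 of 12 measured members lower, median -0.27, -0.33 to -0.23, percentile 0, -0.10 with equal cluster weights). Immature NK genes were higher (9 of 10 measured members higher, median 0.20, 0.15 to 0.26, percentile 100.0, -0.03 with equal cluster weights). NF-kB targets were lower (10 of 11 measured members lower, median -0.21, -0.28 to -0.12, percentile 0.01). Mitochondrially encoded genes (13 of 13 measured members higher, median 0.18, 0.16 to 0.20, percentile 100.0) and ribosomal protein genes (81 of 81 measured members higher, median 0.12, 0.11 to 0.13, percentile 100.0) were slightly higher. In the refed spleen the highest genes further held Nrgn (0.50), Fosb (0.48), Ahsa2 (0.48), Cacybp (0.47) and Chordc1 (0.45). The lowest were Dusp2 (-0.62), Mirt1 (-0.58), Rac3 (-0.57), Ube2c (-0.55), Ccl3 (-0.54), Cirbp (-0.54), Myo6 (-0.54), Kcnj8 (-0.53), Rgs1 (-0.50) and Phactr3 (-0.47). Other NK genes gave smaller ratios: Cpt1a (0.41), Tbx21 (0.09), Eomes (0.13), Cd27 (0.22, -0.02 with equal cluster weights) and Cd69 (0.21) were higher. Lower were S1pr5 (-0.22), Cxcr4 (-0.20), Klf2 (-0.24), Ifng (-0.26), Il12rb2 (-0.08), Gzmb (-0.24), Gzma (-0.22), Prf1 (-0.24), Itgam (-0.33) and Ccl5 (-0.29).

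Refed bone marrow cells differed from ad libitum cells mainly in maturation genes. Mature NK genes were lower (11 of 11 measured members lower, median -0.49, -0.64 to -0.36, percentile 0), with the chymase gene Cma1 (-1.02, -1.34 to -0.71), Klrg1 (-1.04, -1.43 to -0.65) and Gzmb (-0.69, -0.81 to -0.58). Ly49 genes, which encode receptors for major histocompatibility class I, were lower too (7 of 7 measured members lower, median -0.50, -0.55 to -0.18, percentile 0, -0.18 with cells thinned to equal depth). Immature NK genes were higher (10 of 10 measured members higher, median 0.27, 0.22 to 0.35, percentile 100.0), with Ltb (0.78), Tcf7 (0.52, -0.04 with thinned cells) and Cd27 (0.40). The glucocorticoid list (7 of 7 measured members lower, median -0.06, -0.17 to 0.03, percentile 28.4, -0.10 without each gene's highest cell) and the dividing list (7 of 11 measured members lower, median -0.03, -0.10 to 0.00, percentile 29.8, -0.06 without each gene's highest cell) were close to 0. Among the highest genes were also Cd74 (1.89, -0.42 without its highest cell), Cst3 (0.95, 0.06 without its highest cell), Isg15 (0.78, 0.41 without its highest cell, -0.11 with thinned cells, -0.11 with equal cluster weights), Cd3d (0.61), Kbtbd11 (0.57), Mbp (0.52), Midn (0.48), Cd160 (0.46) and Ubxn4 (0.40). The lowest were Plac8 (-0.66), Fgl2 (-0.65), As3mt (-0.60), Sqstm1 (-0.59), Klra9 (-0.58), Sypl (-0.52), Cmas (-0.52), Klra3 (-0.51), Sft2d1 (-0.51, 0.24 with thinned cells) and Klra8 (-0.50). For the chosen NK genes, Ifng (0.15, 0.08 without its highest cell), Eomes (0.01, -0.01 without its highest cell) and Cd69 (0.16) were higher. Lower were S1pr5 (-0.67), Cxcr4 (-0.04, -0.07 without its highest cell), Klf2 (-0.10, -0.23 without its highest cell), Il12rb2 (-0.05), Tsc22d3 (-0.12), Gzma (-0.48), Prf1 (-0.39), Tbx21 (-0.15), Itgam (-0.58) and Ccl5 (-0.28). Dendritic cell markers summed to 193 CPM in the refed and 64.0 CPM in the ad libitum cells.

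In the refed tumour population, immediate early, chemokine and amino acid response genes were higher than in the ad libitum population. Furin, a protease that processes TGF-beta and other precursors, was 1.5996, 0.80 to 2.42, and Ccl3 1.36, 1.001 to 1.74. Immediate early and heat shock genes (17 of 19 measured members higher, median 0.31, 0.21 to 0.44, percentile 100.0), cytokines and chemokines (8 of 9 measured members higher, median 0.45, 0.34 to 0.65, percentile 100.0, 1.03 without each gene's highest cell, 0.00 with the same weight per cell) and the ATF4 amino acid response (10 of 10 measured members higher, median 0.44, 0.25 to 0.70, percentile 100.0) were higher as groups, with Ifng (0.98, 0.68 to 1.28) and Gars (1.04) as members. Glucocorticoid targets lay near 0 (6 of 11 measured members lower, median -0.05, -0.15 to 0.18, percentile 24.7, 0.28 without each gene's highest cell). Spp1 (-2.15), Gzme (-1.66) and Gzmd (-1.57) were lower, and glycolysis (10 of 15 measured members lower, median -0.19, -0.28 to -0.07, percentile 0.150, -0.06 without each gene's highest cell, 0.06 with equal cluster weights) slightly so. The refed tumour cells' highest genes further held Hspa1a (2.18, 0.59 without its highest cell), Cdkn1a (1.56), Ero1l (1.44, 0.12 without its highest cell, -0.14 with thinned cells), Ly6c2 (1.19, 1.84 without its highest cell), Snhg12 (1.15), Zc3h12a (1.14), Dgat1 (1.08), Ccl4 (1.06, 1.599 without its highest cell), Nr4a2 (1.06) and Nfe2l2 (1.05, 1.84 without its highest cell). The lowest were Fabp5 (-3.74, -1.37 without its highest cell), Cenpf (-1.61, -0.60 without its highest cell), Tmsb15a (-1.55, -0.93 without its highest cell), Cdca3 (-1.48), Hmgb3 (-1.40), Klrb1a (-1.28), Anxa5 (-1.26), Adam8 (-1.23) and Ifi27l2a (-1.23, 1.09 without its highest cell, 0.44 with the same weight per cell, 0.11 with thinned cells, 0.33 with equal cluster weights, 0.22 with other cell types kept). Remaining NK genes: Cxcr4 (0.42, 0.71 without its highest cell), Klf2 (0.50, 1.03 without its highest cell), Tsc22d3 (0.29), Gzmb (0.33, 0.55 without its highest cell), Gzma (0.02, 0.25 without its highest cell), Tbx21 (0.28, 0.48 without its highest cell), Cd27 (0.51, 0.77 without its highest cell), Ccl5 (0.04, 0.26 without its highest cell) and Cd69 (0.31, 0.66 without its highest cell) were higher. Lower were Il12rb2 (-0.47, -0.30 without its highest cell), Prf1 (-0.17, 0.01 without its highest cell), Eomes (-0.23, -0.11 without its highest cell) and Klrg1 (-0.30, -0.00199 without its highest cell).

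The refed populations were also set directly against the fasted ones. This comparison and that of fasted with ad libitum cells share the same fasted sample. Any trait of that sample appears in both with opposite sign, so opposite signs alone do not show a return after refeeding. Glucocorticoid targets were lower after refeeding in spleen (12 of 12 measured members lower, median -0.96, -1.06 to -0.81, percentile 0), bone marrow (10 of 10 measured members lower, median -1.253, -1.55 to -1.01, percentile 0) and tumour (9 of 12 measured members lower, median -0.58, -0.76 to -0.36, percentile 0, -0.27 with equal cluster weights). Pik3ip1 was -1.83, -2.07 to -1.597 in spleen and -2.21, -2.75 to -1.65 in bone marrow, and Tsc22d3 -1.64, -1.78 to -1.51, -2.06, -2.41 to -1.70 and -1.69, -1.96 to -1.43 in spleen, bone marrow and tumour. Cpt1a was -0.92 in spleen and -1.44 in bone marrow. In spleen, the endoplasmic reticulum chaperone genes Pdia6 (1.06, 0.92 to 1.20) and Calr (1.05, 0.95 to 1.15) and Xcl1 (1.16, 1.07 to 1.251) were higher after refeeding. As groups, dividing genes (9 of 9 measured members higher, median 0.62, 0.53 to 0.78, percentile 100.0, -0.11 with equal cluster weights), MYC and nucleolar growth genes (14 of 15 measured members higher, median 0.32, 0.25 to 0.43, percentile 100.0), interferon-induced genes (5 of 5 measured members higher, median 0.35, 0.23 to 0.50, percentile 99.8) and oxidative phosphorylation genes (28 of 29 measured members higher, median 0.22, 0.18 to 0.26, percentile 100.0) were higher in spleen. The spleen's highest genes further held Top2a (1.13, -0.14 with equal cluster weights), Tuba1b (1.05), Gzmc (1.02, 0.44 without its highest cell), Hsp90ab1 (0.98), Stip1 (0.97), Hsph1 (0.91), Sdf2l1 (0.88), Fkbp2 (0.87) and Tnfrsf9 (0.86). Equal cluster weights again left out the dividing-like cluster of the spleen, with 22 refed and 4 fasted cells. The lowest were Rab27a (-1.13), Klhl6 (-1.12), Ddit4 (-1.11), Txnip (-1.09), Cxcr4 (-0.96), Acp5 (-0.92), Qrfp (-0.92), Zfp36l2 (-0.92), Serinc3 (-0.90) and Mirt1 (-0.90). Further NK genes in spleen: Ifng (0.05, -0.00107 without its highest cell), Gzmb (0.19), Prf1 (0.02), Tbx21 (0.20), Eomes (0.16) and Cd69 (0.35) were higher. Lower were S1pr5 (-0.06), Klf2 (-0.30), Il12rb2 (-0.11), Gzma (-0.08, 0.01 with the same weight per cell, 0.00101 with thinned cells, 0.09 with equal cluster weights), Cd27 (-0.13), Itgam (-0.29), Klrg1 (-0.14) and Ccl5 (-0.53).

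Refed against fasted bone marrow cells had higher Mcm5 (2.13, 1.41 to 2.87), Rfc4 (1.92), Hells (1.82) and Tk1 (1.82). They were higher in dividing genes (11 of 11 measured members higher, median 0.98, 0.87 to 1.09, percentile 100.0, -0.09 with equal cluster weights). That last value left out the cluster led by replication genes, with 36 refed and 0 fasted cells. MYC and nucleolar growth genes were higher (14 of 15 measured members higher, median 0.67, 0.55 to 0.83, percentile 100.0), as were genes of oxidative phosphorylation (28 of 29 measured members higher, median 0.43, 0.37 to 0.52, percentile 100.0). Genes of FOXO and KLF2 quiescence were lower (14 of 14 measured members lower, median -0.43, -0.66 to -0.31, percentile 0.170), with Il7r at -2.87, -3.40 to -2.27. The lowest genes further held S100a9 (-8.06, -0.45 without its highest cell), S100a8 (-8.03, -0.60 without its highest cell), Camp (-7.69, -0.64 without its highest cell), Ngp (-7.09, 0.11 without its highest cell), Lcn2 (-6.70, 0 without its highest cell), Chil3 (-6.36, 0.11 without its highest cell), Lyz2 (-5.07, -0.24 without its highest cell), Ltf (-5.07, 0 without its highest cell), Wfdc21 (-4.67, 0.11 without its highest cell), Serpinb1a (-2.99, -1.16 without its highest cell) and Pik3ip1 (-2.21), most of them the neutrophil genes of 1 fasted cell. Among the highest were also Cd74 (2.69, 0.17 without its highest cell), Aurkb (1.76), Lyar (1.71), Ppa1 (1.58), Sdf2l1 (1.57), Dut (1.57), Rfc5 (1.49) and Dctpp1 (1.48). Of the chosen NK genes, Ifng (1.06), Il12rb2 (0.55) and Gzmb (0.66) were higher. Lower were S1pr5 (-0.40, -0.20 without its highest cell), Cxcr4 (-1.11), Klf2 (-0.17), Gzma (-0.01, 0.03 without its highest cell), Prf1 (-0.01, 0.07 without its highest cell), Tbx21 (-0.23), Eomes (-0.16), Cd27 (-0.40), Itgam (-1.09), Ccl5 (-0.91) and Cd69 (-0.19, -0.12 without its highest cell).

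Tumour cells of the refed population were higher than fasted ones in glycolysis (15 of 15 measured members higher, median 0.78, 0.67 to 0.83, percentile 100.0), sterol and fatty acid synthesis (11 of 11 measured members higher, median 0.84, 0.68 to 1.05, percentile 100.0), hypoxia (12 of 13 measured members higher, median 0.78, 0.50 to 0.88, percentile 100.0, 0.34 without each gene's highest cell) and dividing genes (11 of 11 measured members higher, median 0.72, 0.60 to 0.85, percentile 100.0, 0.40 without each gene's highest cell, 0.10 with equal cluster weights). The glycolysis and hypoxia lists share Ldha, Pgk1 and Slc2a1 and had the same median. Spp1 (1.79, 1.62 to 1.95), Slc16a3 (1.68) and Gzme (1.43) were among the highest genes. Cxcr4 (-1.89, -2.16 to -1.62), Ccl5 (-1.44, -1.49 to -1.39) and Klf2 (-1.28, -1.45 to -1.11) were lower. So were genes of FOXO and KLF2 quiescence (11 of 12 measured members lower, median -0.56, -0.79 to -0.40, percentile 0, -0.16 with equal cluster weights) and the TGF-beta and residency list (6 of 8 measured members lower, median -0.51, -0.57 to -0.33, percentile 0.01, -0.10), whereas mature NK genes were higher (5 of 7 measured members higher, median 0.39, 0.29 to 0.47, percentile 99.8). The highest genes of this comparison further held Gzmg (2.43), Ero1l (2.21, 0.79 without its highest cell), Basp1 (2.20), Myo10 (2.08), Ifitm3 (1.92), Fdps (1.65), Ifitm2 (1.63), Mt1 (1.47) and Hspa1a (1.44, -0.07 without its highest cell). The lowest were Ahr (-2.02), Klrb1a (-1.95), Tsc22d3 (-1.69), Cited4 (-1.68), Ccl1 (-1.67, -2.95 without its highest cell, 0.92 with the same weight per cell, 0.16 with thinned cells), Pdcd4 (-1.59), Zfp36l2 (-1.40), Mirt1 (-1.30), Ifit3 (-1.29) and Prex1 (-1.28). As for the chosen NK genes, Ifng (0.37), Gzmb (0.79), Prf1 (0.91), Tbx21 (0.10, 0.05 without its highest cell), Eomes (0.22), Cd27 (0.22, 0.11 without its highest cell) and Klrg1 (0.75) were higher. Lower were Il12rb2 (-0.82), Gzma (-0.55) and Cd69 (-0.53).

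The ad libitum spleen population, the same sample as in the diet comparisons, was also set against the naive spleen population. It had higher genes of mature and interferon-exposed NK cells. Cx3cr1 was 0.71, 0.47 to 0.96, Gzmb 0.57, 0.51 to 0.63 and Isg15, an interferon-induced ubiquitin-like protein, 0.72, 0.49 to 0.95. Mature NK genes (10 of 12 measured members higher, median 0.20, 0.15 to 0.27, percentile 100.0, 0.09 with equal cluster weights) and interferon-induced genes (5 of 5 measured members higher, median 0.43, 0.20 to 0.57, percentile 100.0) were higher, and immature NK genes lower (11 of 11 measured members lower, median -0.29, -0.35 to -0.16, percentile 0, -0.16 with equal cluster weights), with Tcf7, a transcription factor of early NK cells (-0.51), Kit (-0.57) and Ltb (-0.46). Gzmc (1.11, 0.95 to 1.26, -0.02 with thinned cells, -0.08 with equal cluster weights) headed the ratios, and 21.3% of its ad libitum UMIs came from 1 cell. The glucocorticoid list was slightly higher (8 of 10 measured members higher, median 0.21, 0.10 to 0.31, percentile 100.0). Heat shock genes Chordc1 (-0.57) and Hsph1 (-0.53) were lower. The highest genes further held ERDR1 (0.71), Rgs1 (0.59), Plac8 (0.58), Ccl3 (0.58), Serpinb9b (0.51), Pkp3 (0.47), Odc1 (0.47) and Ly6c2 (0.47). The lowest were G0s2 (-0.50), Fam177a (-0.47), St8sia4 (-0.45), Fosb (-0.45), Cxxc5 (-0.44), Cxcr3 (-0.43), Ahsa2 (-0.41) and Smad4 (-0.40). For the remaining NK genes, Cxcr4 (0.50), Klf2 (0.03), Ifng (0.30), Il12rb2 (0.24), Tsc22d3 (0.27), Gzma (0.24), Prf1 (0.28), Tbx21 (0.02, 0.03 without its highest cell), Itgam (0.11), Klrg1 (0.37), Ccl5 (0.10) and Cd69 (0.02, 0.03 without its highest cell) were higher. Lower were S1pr5 (-0.09), Eomes (-0.19) and Cd27 (-0.29).

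Shares of cells were compared after thinning each cell to 1500 UMIs, with exact binomial 95% intervals. Cells with 3 or more UMIs of the dividing list made up 45.3% (40.8 to 49.9%, 216 of 477) of the ad libitum, 23% (15.2 to 32.5%, 23 of 100) of the fasted and 42.2% (36.2 to 48.3%, 113 of 268) of the refed bone marrow cells. The same measure gave 21 of 162 (13.0%, unthinned 83.1%) of T cell-like and 11 of 49 (22.4%, unthinned 71.2%) of monocyte or macrophage-like cells of these libraries. It gave 10 of 44 (22.7%, unthinned 76.1%) of dendritic cell-like and 13 of 25 (52.0%, unthinned 96.0%) of neutrophil-like cells. As stated for the clusters, the name dendritic cell-like is uncertain, because that cluster carried the macrophage genes Apoe, C1qa and C1qb too. Free RNA was not separated from expression for this measure, so it is not read as the share of cells that divide. Unthinned, the bone marrow shares were 85.3, 63.3 and 85.1%. Thinning left out 20, 20 and 13 shallower bone marrow cells. In spleen the thinned dividing share was 26.1% (24.0 to 28.3%) ad libitum and 24.7% (22.3 to 27.2%) fasted. With 5 or more UMIs it was 6.26 and 3.56%, and unthinned 75.6 and 67.6%. In tumour the thinned share was 16.7% (5.64 to 34.7%, 5 of 30) ad libitum and 15.5% (12.9 to 18.3%) fasted, and unthinned 48.8 and 76.3%. Thinned at 3 or more UMIs, no lower fasted share was therefore clear in spleen or tumour. Cd27, a receptor of immature NK cells, was detected in 15.9% (12.8 to 19.5%, 76 of 477) of ad libitum, 30.0% (21.2 to 40.0%, 30 of 100) of fasted and 18.3% (13.8 to 23.4%, 49 of 268) of refed bone marrow cells. It was detected in 48 of 162 (29.6%, unthinned 79.5%) of T cell-like and 9 of 49 (18.4%, unthinned 42.4%) of monocyte or macrophage-like cells. Lower shares came from the rest, 0 of 44 (0%, upper limit 8.04%, unthinned 13.0%) of dendritic cell-like and 1 of 25 (4.00%, unthinned 20%) of neutrophil-like cells. The interval of the monocyte or macrophage-like share, 8.76 to 32.0%, held all 3 NK shares, so no difference from that cell type was detectable at this depth. Most cells of that cluster came from spleen, with 14 ad libitum, 19 fasted, 14 refed and 7 naive cells. The bone marrow gave it 2 ad libitum, 0 fasted and 2 refed cells. It is therefore not a background of the same tissue as the bone marrow NK cells. Unthinned, the NK shares were 53.5, 55.0 and 62.6%. In spleen, Klrg1 was detected in 22.4% (20.4 to 24.5%, 372 of 1661) of ad libitum, 15.7% (13.7 to 17.8%, 198 of 1263) of fasted, 13.9% (12.1 to 15.9%, 188 of 1353) of refed and 16.0% (13.4 to 18.8%, 120 of 751) of naive cells. It was detected in 1 of 162 (0.617%, unthinned 4.22%) of T cell-like and 8 of 49 (16.3%, unthinned 27.1%) of monocyte or macrophage-like cells. After thinning none of the remaining cells held it, 0 of 44 (0%, upper limit 8.04%, unthinned 2.17%) of dendritic cell-like and 0 of 25 (0%, upper limit 13.7%, unthinned 4.00%) of neutrophil-like cells. All 4 NK shares lay inside the interval of the monocyte or macrophage-like share, 7.32 to 29.7%, and above that of the T cell-like share. Unthinned, it was detected in 42.2, 28.8, 30.8 and 32.2% of spleen cells in that order. Thinning left out 111, 99, 100 and 48 of these cells. The median depths were 6846 and 4327.5 UMIs in ad libitum and fasted bone marrow NK cells. For other cell types they were 7574.5 in T cell-like, 4256 in monocyte or macrophage-like, 11685 in neutrophil-like and 9766 in dendritic cell-like cells. They were 4197 and 3448.5 in ad libitum and fasted spleen NK cells.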

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

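Every test of an explanation in this part was chosen after the results were seen, and intervals of medians in brackets come from drawing the cells of each population again. The pattern weighed first is that glucocorticoid targets were higher in the fasted than in the ad libitum population of each tissue. Low-RNA cells, another mix of clusters and another depth per cell are technical explanations, and without low-RNA clusters, with equal cluster weights and with thinned cells the medians were 1.22 (0.86 to 1.57), 1.247 (0.88 to 1.47) and 0.86 (0.61 to 1.48) in bone marrow and 0.76 (0.62 to 0.97), 0.95 (0.76 to 1.10) and 1.08 (0.76 to 1.15) in spleen. These intervals kept at least 0.5 times the median of all cells, which argues against the 3 explanations there, and as a hypothesis fasting raised glucocorticoid signalling in NK cells of these 2 tissues. The glucocorticoid list shares Pik3ip1, Il7r and Btg1 with the list of FOXO and KLF2 quiescence. No test separated glucocorticoid signalling from FOXO and KLF2 quiescence. In tumour the medians were 0.63 (0.15 to 1.19), 0.36 (-0.17 to 0.95) and 0.75 (0.46 to 1.94), and all 3 explanations stay open, the first 2 because of the wide intervals and the last because 4 of 12 genes held fewer than 3 UMIs in a thinned population. A difference between mice, harvest times or handling stays open too, since each population was 1 sample and the biological difference of the design stays untested.

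A signal in cells outside the comparisons raised the next point. Of the 1963 cells in the authors' cluster 0, 1574 (80.2%, 78.3 to 81.9%) were called doublets, and 332 of its 386 singlets came from tumour. Droplets with 2 cells should hold more UMIs, but the median of the called doublets was 1.03 times that of the singlets. Their summed spleen genes, 1596 CPM against 1574 CPM in all singlets of the cluster, lay at 0.340 of the way from its tumour singlets to spleen singlets, and their summed tumour genes at 1.27 times the tumour singlets' level. The UMIs speak against droplets of 2 cells as the whole cause. For a spleen cell in the same droplet the predictions conflict, since 0.340 met the level set for it and the UMIs the level set against it. A spleen cell in part of the droplets therefore stays open, as do single tumour cells with more than 1 hashtag named. No biological explanation was tested.

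Also weighed was that glycolysis and sterol synthesis genes were lower in the fasted than in the ad libitum tumour population. A few cells with very many UMIs would lose the pattern once every cell had the same weight, and the medians were then -0.85 (-1.17 to -0.33) for glycolysis and -0.86 (-1.28 to -0.14) for sterol synthesis. Another share of the high-UMI granzyme cluster would lose it under equal cluster weights, which gave -0.41 (-0.67 to -0.02) for glycolysis and -0.59 (-1.10 to 0.11) for sterol synthesis. With intervals this wide from 43 ad libitum cells, both explanations stay open for both lists, and the biological difference of the design stays untested.

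The other points were raised by ratios of opposite sign in 2 tissues, and these differences were not tested. For a list, the value is the median over its members measured in both tissues of each member's difference, which can depart from the difference of the 2 medians in brackets. For fasted against ad libitum, the tumour ratio minus the spleen ratio was 0.91 (0.61 and -0.14) for cytokines and chemokines, 0.62 (0.54 and -0.12) for the TGF-beta response and residency list, 0.63 (0.41 and -0.14) for NF-kB targets, 0.87 (0.23 and -0.42) for interferon-responding genes, 0.91 (0.61 and -0.31) for Ifng and 0.71 (0.56 and -0.15) for Gzma. The difference of the cytokine and chemokine list equals that of its member Ifng, so they are not separate points. The bone marrow ratio minus the tumour ratio was -0.86 (-0.67 and 0.19) for the ATF4 amino acid response, -0.59 (-0.43 and 0.23) for interferon-responding genes, -1.52 (-0.91 and 0.61) for Ifng and -1.03 (-0.47 and 0.56) for Gzma. For refed against ad libitum, tumour minus spleen was 0.74 (0.50 and -0.24) for Klf2, 1.24 (0.98 and -0.26) for Ifng and 0.57 (0.33 and -0.24) for Gzmb, and bone marrow minus tumour was -1.02 (-0.69 and 0.33) for Gzmb.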

How the results depend on the processing

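A value counted as turned only where the main interval left out 0. By that rule no alternative turned 403 of 442 single-gene ratios and 74 of 86 list medians and their differences. Sign changes of results whose interval held 0 were not counted, so these numbers do not mean that every direction was kept. Of 6630 gene values under alternatives, 5660 stayed inside the counting interval, 917 moved out of it with the same direction or from an interval that held 0, and 53 turned. For lists these numbers were 1268, 261 and 13 of 1542. Keeping every cell classified to 1 population repeated the main values, since the filters removed 0 cells. A minimum of 1000 UMIs and other cluster resolutions left all 442 gene values inside. Thinned cells left 219 and equal cluster weights 231 of 442 inside, and for lists 47 and 31 of 86. The pooled counts therefore overstate how stable the ratios were under those 2 settings. Correlations across genes moved in 29 of 108 values and never turned. The smallest populations, with 43 and 91 tumour and 120 bone marrow cells, limit what depth can resolve. Scrublet predicted 0 doublets, so leaving these out gave no value, and a minimum of 100 CPM left 6 list results without one. Low-RNA clusters, highest Scrublet scores and highest cells were chosen after the data were seen. The values that turned, and those of the main results that left their interval, follow by setting (AL, ad libitum), and the cause was not tested. TMM factors gave glucocorticoid targets 0.90 (tumour fasted against AL), and Gzma 0.00334 (spleen refed against fasted). Totals without ribosomal protein and mitochondrial genes gave mature NK -1.34 (bone marrow AL against spleen AL), and glucocorticoid targets 0.90 (tumour fasted against AL). Keeping cells of other types gave Lyz2 -0.54 (bone marrow fasted against AL), and glucocorticoid targets 0.86 (tumour fasted against AL). In tumour refed against AL it gave Ifi27l2a 0.22. The same weight per cell gave mature NK -1.19 (bone marrow AL against spleen AL), and interferon-responding 2.82 (tumour AL against spleen AL). For spleen fasted against AL it gave glucocorticoid targets 0.94, Gzmc 0.0540 and Klf2 -0.00587, and glucocorticoid targets 0.26 (tumour fasted against AL). For fasting, bone marrow minus spleen it gave glucocorticoid targets 0.14, and glucocorticoid targets -0.27 (fasting, tumour minus spleen). For spleen refed against AL it gave immediate early and heat shock 0.38, and mature NK -0.66 (bone marrow refed against AL). For tumour refed against AL it gave cytokines and chemokines -0.00290 and Ifi27l2a 0.44, and Gzma 0.00868 (spleen refed against fasted). For tumour refed against fasted it gave Ccl1 0.92. Cells thinned to equal depth gave mature NK -1.22 (bone marrow AL against spleen AL), and interferon-responding 2.27 (tumour AL against spleen AL). In spleen fasted against AL it gave glucocorticoid targets 1.08 and Klf2 -0.0154, and glucocorticoid targets 0.86 (bone marrow fasted against AL). In tumour fasted against AL it gave Cd69 -0.23, Cyp51 1.52, Hmgcs1 1.52 and Eomes 0.16, and glucocorticoid targets 0.14 (fasting, bone marrow minus spleen). In bone marrow refed against AL it gave Tcf7 -0.0444, Isg15 -0.11 and Sft2d1 0.24, and Ero1l -0.14 and Ifi27l2a 0.11 (tumour refed against AL). In spleen refed against fasted it gave glucocorticoid targets -1.09 and Gzma 0.00101, and Ccl1 0.16 (tumour refed against fasted). In spleen AL against naive it gave Gzmc -0.0184. Equal cluster weights gave Nusap1 -1.20 (bone marrow AL against tumour AL), and Fbxo5 -0.34, Hist1h2ae -0.0349, Hist1h2ab -0.32, Hist1h2bj -0.0355, mature NK -0.21 and dividing -0.22 (bone marrow AL against spleen AL). For tumour AL against spleen AL it gave Gzme -0.58, Gzmg -0.32, Gzmf -1.47 and interferon-responding 1.08, and glucocorticoid targets 0.95, dividing 0.0866, Mki67 0.11, Birc5 0.17, Gzmc 0.17, Ube2c 0.15 and Stmn1 0.0549 (spleen fasted against AL). For bone marrow fasted against AL it gave dividing 0.12, and Cd69 -0.29 and dividing 0.16 (tumour fasted against AL). For fasting, bone marrow minus spleen it gave glucocorticoid targets 0.0445, and glucocorticoid targets -0.46 (fasting, tumour minus spleen). For spleen refed against AL it gave immature NK -0.0254 and Cd27 -0.0233, and Isg15 -0.11 (bone marrow refed against AL). For tumour refed against AL it gave glycolysis 0.0551 and Ifi27l2a 0.33, and glucocorticoid targets -0.27 (tumour refed against fasted). For spleen refed against fasted it gave dividing -0.11, Top2a -0.14 and Gzma 0.0913, and dividing -0.0858 (bone marrow refed against fasted). For spleen AL against naive it gave mature NK 0.0932 and Gzmc -0.0786, and Gzmd -1.59 (tumour fasted against bone marrow fasted). For bone marrow fasted against spleen fasted it gave dividing -0.29. A pseudocount of 1 CPM gave glucocorticoid targets -1.07 (spleen refed against fasted). A pseudocount of 20 CPM gave mature NK -1.30 (bone marrow AL against spleen AL), and interferon-responding 1.30 (tumour AL against spleen AL). For spleen fasted against AL it gave glucocorticoid targets 0.58, and glucocorticoid targets 0.90 (bone marrow fasted against AL). For spleen refed against fasted it gave glucocorticoid targets -0.64, and glucocorticoid targets -0.95 (bone marrow refed against fasted). A minimum of 10 CPM gave glucocorticoid targets 0.85 (tumour fasted against AL), and immediate early and heat shock 0.15 (spleen refed against AL). A minimum of 100 CPM gave mature NK -1.79 (bone marrow AL against spleen AL), and interferon-responding 2.22 (tumour AL against spleen AL). For spleen fasted against AL it gave glucocorticoid targets 0.65, and glucocorticoid targets 0.93 (tumour fasted against AL). For spleen refed against fasted it gave glucocorticoid targets -0.75, and glucocorticoid targets -0.82 (tumour refed against fasted). For spleen AL against naive it gave mature NK 0.15. Without a minimum the values were glucocorticoid targets 0.49 (spleen fasted against AL), and mature NK 0.00397 (tumour fasted against AL). In spleen refed against AL it gave immediate early and heat shock 0.15, and glucocorticoid targets -0.66 (spleen refed against fasted). In bone marrow refed against fasted it gave glucocorticoid targets -0.95. Clusters at resolution 0.4 gave glucocorticoid targets 0.85 (tumour fasted against AL). Leaving out the cells of highest Scrublet score gave mature NK -1.57 (bone marrow AL against spleen AL). Leaving out each gene's highest cell gave interferon-responding 1.40 (tumour AL against spleen AL), and Ngp -0.39, Lcn2 -0.18, Chil3 -0.24, Lyz2 -0.51 and Wfdc21 -0.18 (bone marrow fasted against AL). For tumour fasted against AL it gave glucocorticoid targets 1.13, and glucocorticoid targets 0.94 (fasting, tumour minus spleen). For bone marrow refed against AL it gave Cd74 -0.42, and immediate early and heat shock 0.45 and Ifi27l2a 1.09 (tumour refed against AL). For tumour refed against fasted it gave glucocorticoid targets -0.76 and Hspa1a -0.0654, and Ngp 0.11, Chil3 0.11 and Wfdc21 0.11 (bone marrow refed against fasted). Thinning to 1000 UMIs gave shares of dividing 35.8% in bone marrow AL, 35.5% in bone marrow refed, Cd27 12.1% in bone marrow AL, Klrg1 15.2% in spleen AL, 10.8% in spleen fasted, 10.9% in spleen refed, 11.6% in spleen naive. Thinning to 2500 UMIs gave shares of dividing 62.5% in bone marrow AL, 36.6% in bone marrow fasted, 60.3% in bone marrow refed, Cd27 25.7% in bone marrow AL, 43.9% in bone marrow fasted, 30.0% in bone marrow refed, Klrg1 31.2% in spleen AL, 24.1% in spleen fasted, 22.98% in spleen refed, 22.7% in spleen naive. Unthinned shares were dividing 85.3% in bone marrow AL, 63.3% in bone marrow fasted, 85.1% in bone marrow refed, Cd27 53.5% in bone marrow AL, 55.0% in bone marrow fasted, 62.6% in bone marrow refed, Klrg1 42.2% in spleen AL, 28.8% in spleen fasted, 30.8% in spleen refed, 32.2% in spleen naive. With 2 or more UMIs of the list the shares were dividing 63.1% in bone marrow AL, 48.0% in bone marrow fasted, 57.8% in bone marrow refed. With 5 or more UMIs they were dividing 34.0% in bone marrow AL, 11% in bone marrow fasted, 32.5% in bone marrow refed.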

Other observations

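Tissue differences were also measured among fasted cells. Higher in fasted tumour cells than in the other tissues were Gzmc (log2 ratio 6.13, 6.02 to 6.25 against the next highest tissue), Gzmd (4.74, -1.59 with equal cluster weights), Ccl1 (4.56), Isg20 (3.95) and Ly6a (3.98). Fasted spleen cells had higher Kcnj8 (log2 ratio 2.55, 2.24 to 2.85), S1pr5 (2.34), Klrg1 (2.22) and Zeb2 (2.05). Interferon-responding genes were higher in fasted tumour than in fasted spleen cells (14 of 14 measured members higher, median 2.55, 2.36 to 2.67, percentile 100.0), and mature NK genes lower (9 of 12 measured members lower, median -1.83, -2.01 to -1.64, percentile 0). Between fasted bone marrow and fasted spleen, mature NK genes were lower in bone marrow (11 of 12 measured members lower, median -1.63, -1.83 to -1.36, percentile 0, -0.23 with equal cluster weights) and dividing genes higher (11 of 11 measured members higher, median 1.79, 1.61 to 2.07, percentile 100.0, -0.29 with equal cluster weights). TMM factors moved the median of all genes by 0.30 for fasted tumour against fasted spleen. For Gzmd, equal cluster weights left out the cluster led by granzyme genes, with 78 tumour and 0 bone marrow cells. For the dividing genes they left out the dividing-like cluster, with 11 bone marrow and 4 spleen cells.

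Calls of doublets differed between the authors' clusters. Beside cluster 0, they were most frequent in cluster 11 (62.4%) and cluster 8 (59.0%), and least frequent in cluster 5 (22.6%). The refed ratios of single genes, unlike the fasted ones, had correlations across genes of 0.17 between bone marrow and spleen and 0.05 between tumour and spleen.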
